A study of Homo sapiens with 2 samples.

How the data were processed

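The series consists of 2 RIP-seq libraries from Huh-7 cells, 1 IP and 1 input, grouped by their titles. Per the labels, 10% of the lysate served as input and 90% went into the IP, RNA was extracted with TRIzol, a stranded mRNA kit with molecular tags of 8 random bases was used, and library products of 200 to 500 base pairs were sequenced in paired-end mode. The design text names an anti-SRSF7 antibody, the treatment label of the IP library reads SPSF7, and the sample protocol names an anti-YTHDF2 antibody and poly(A) selection before the IP. Both statements cannot hold for the same IP, and the files do not settle it.

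Reads were trimmed with Trimmomatic and aligned with STAR 2.5.3a, per the submitters' processing notes. The gene counter, the annotation, the peak caller and the genome build are not given in the sources used here. The gene expression values are RPKM, deposited by the authors in a table whose header gives no unit. Value times gene length sums to the same total in both columns, which is what RPKM gives. Low counts of blood and heart genes, recovered as below, were mostly even, such as MB (2 IP and 0 input reads), MYL2 (4 and 8), S100A12 (4 and 10) and CXCR1 (20 and 2). Odd ones, such as NPPA with 5 IP reads, were few. Counting both mates of a pair as reads would give this, and counting fragments (FPKM) would not. Intervals that take reads as independent are then too narrow. All values were whole multiples of the value of 1 read within 0.01 of a read (100% in both libraries), so that whole reads were recovered from them: 5897293 in the IP and 2782045 in the input, with 2022 and 4881 genes at 0. These recovered reads gave the depth and the intervals, and no count model was fitted. The deposited table has 0 columns of other samples, 0 genes on the mitochondrial chromosome and 1 entry per symbol. Of its genes, 4143 share exon bases with another gene on the same strand (21.8% of IP and 35.4% of input reads), and reads of such genes can be counted for both, as for RN7SK and AL162581.1. RNA classes came from the RefSeq gene table of GRCh38.p14, which matched 19804 symbols and left 5752 unmatched. Gene length is the length of merged exons in the deposited table, which exceeds that of the mature mRNA where isoforms differ.

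The peak table gives, per the file headers, a fold enrichment (ratio), a p-value, a false discovery rate and a score for each peak. Peaks were called by the authors from 1 IP and 1 input, with no replicate. All deposited peaks had a fold of at least 2 and a p-value of at most 0.05, the false discovery rate reached 0.0865 and exceeded 0.05 for 3034 peaks, and the deposited score is -log2 of that rate. Peak numbers ran to 9972, of which 2329 were absent from the list. Whether a filter had removed them is not given in the sources used here. The genomic span of a peak (median 351 bases, 51 to 233239) includes introns; the median peak covered 176 exonic bases. How the folds were scaled between the libraries is not given in the sources used here, and folds above 20 were whole multiples of 2.12, the ratio of assigned IP to input reads (also 2.12). What such folds measure is not known here.

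The main value per gene was log2((IP + 1)/(input + 1)) on RPKM, which understates the change of low genes, for genes with a mean of both libraries of at least 1. Single genes are given as the ratio of RPKM values without the pseudocount, with an exact (Clopper-Pearson based) 95% interval of the ratio of both read counts; where a library had 0 reads, reads alone are given. Shares of reads and peaks have exact binomial intervals. The molecular tags remove PCR copies only if they were used in counting, which is not stated for these tables. For each of 26 gene lists, of which 25 had measured members, the median log2 ratio, its order-statistic interval over genes and, with 5 or more genes, its percentile among 10000 random lists matched on mean expression in 20 bins (seed 1) were computed. The list of mitochondrially encoded mRNAs had 0 genes in the table. A peak was placed in the gene with the most exonic overlap on its strand (at least 1 base), and its centre was located along the merged exons and compared with 100 random placements. No p-value was computed, since each group has 1 library and genes are not replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

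The named genes followed a rule fixed, like the groups, the lists and the first set of other settings, at the outset: SRSF7, SRSF3 and YTHDF2; the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 5 RPKM; the 10 highest folds among peaks at or below the median p and the 5 genes with the most peaks; and in each list the 2 highest and 2 lowest members. Not every gene this rule takes is described. Well-covered protein-coding genes (at least 100 reads), structural RNAs, the peaks with the smallest p, JUN and CEBPA were named after their values were seen. The planned shares of peaks in untranslated, coding and intronic regions were replaced by 3 equal parts of the merged exons, and the planned motif counts were not run, because no genome sequence or coding annotation was used here. The settings tried from that first set were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5, centring, scaling to the same RPKM sum, unmatched random lists, peaks with a fold of at least 4, peaks at or below the median p and merged peaks. Scaling by a trimmed mean of M values (30% of M and 5% of A values trimmed per side), scaling to protein-coding reads, at least 100 reads, protein-coding genes alone, genes sharing no exon bases, length-matched lists, a false discovery rate of at most 0.05 and peaks without folds above 20 were added after the data were seen.

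The calculations were tested on simulated data: Poisson reads for the same genes and library sizes with 200 genes changed, 50 per fold size. Of 14151 simulated genes for the comparison per gene, 98.0% of those with a 4-fold increase, 28.0% of those with a 2-fold increase and 2.08% of those with a 1.5-fold increase were called at least 2-fold higher, as were 2.05% of unchanged genes, and 85.7% of those at 0.25 times were called lower. The counting interval held the true ratio for 96.2% of unchanged genes. A list of 20 genes raised 1.5-fold lay at percentile 100, and 1.50% of 200 unchanged lists lay beyond the outer percentiles (2.5 and 97.5). Unchanged genes differed here by counting error only, and 1.95% of them were called at least 2-fold lower. Real genes spread more widely, with 1592 of 14057 at least 2-fold higher and 1159 lower. How well a list raised 1.5-fold would stand out among real genes was therefore not tested. At this depth, single genes near 1 RPKM carry wide intervals, and deeply covered genes carry narrower ones.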

Results

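RNA from an immunoprecipitation (IP), described in the design text as one of the splicing factor SRSF7, was profiled in Huh-7 cells, an established human hepatocellular carcinoma line that expresses fetal and adult liver genes. SRSF7 is a serine/arginine-rich (SR) protein that binds pre-mRNA and takes part in splicing, 3′ end processing and mRNA export. In RNA immunoprecipitation sequencing (RIP-seq), a protein is precipitated from a cell lysate with an antibody and the RNA that comes with it is sequenced beside the RNA of the whole lysate, the input. The series held 2 libraries, 1 IP and 1 input. The design text names an antibody against SRSF7 for the IP, while the sample protocol names an antibody against the m6A reader YTHDF2 after poly(A) selection, so the libraries are called here the IP and the input as labelled. The IP held 5897293 reads assigned to genes and the input 2782045, and the table listed 25556 genes with a median of 20 and 8 reads per gene. With 1 library per group, no difference below has a replicate check. Intervals are 95% intervals, and those of single genes and of read shares cover counting error only, not the choice of scaling between the libraries. The intervals of single genes and of read shares also take reads as independent. Low counts of blood and heart genes were mostly even, as counting both mates of a pair would give, so these intervals are likely too narrow.

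7SL, 7SK and RNase P RNA took a far smaller part of the IP than of the input, and protein-coding genes a larger one. 7SL RNA, the RNA core of the signal recognition particle (RN7SL1 and RN7SL2), made up 11.02% of input reads (exact binomial interval 10.98 to 11.05%) and 0.359% of IP reads (0.354 to 0.364%). 7SK RNA, the scaffold that holds the elongation factor P-TEFb inactive, made up 2.16% of input reads and 0.221% of IP reads. RPPH1, the RNA of RNase P, stood at 0.140 times its input level (interval 0.130 to 0.150), and RMRP, the RNA of RNase MRP, at 0.600 times (0.555 to 0.650). Reads assigned to nuclear copies of mitochondrial genes made up 1.68% of input and 0.258% of IP reads, led by MTATP6P1 at 0.136 times its input level (0.133 to 0.139). Whether these reads came from the copies or from mitochondrial RNA, whose own genes are absent from the table, was not tested. Protein-coding genes made up 90.6% of IP and 69.2% of input reads, and long non-coding RNA genes 1.402% and 1.16%. The nuclear-retained MALAT1 was at 1.72 times its input level (1.66 to 1.78) and NEAT1, the scaffold of paraspeckles, at 0.987 times (0.877 to 1.11). The same 7SL and 7SK reads were also counted for overlapping clone-named genes, which held a further 8.13% of input and 0.457% of IP reads, and the table listed 0 genes on the mitochondrial chromosome.

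**Figure D1:**
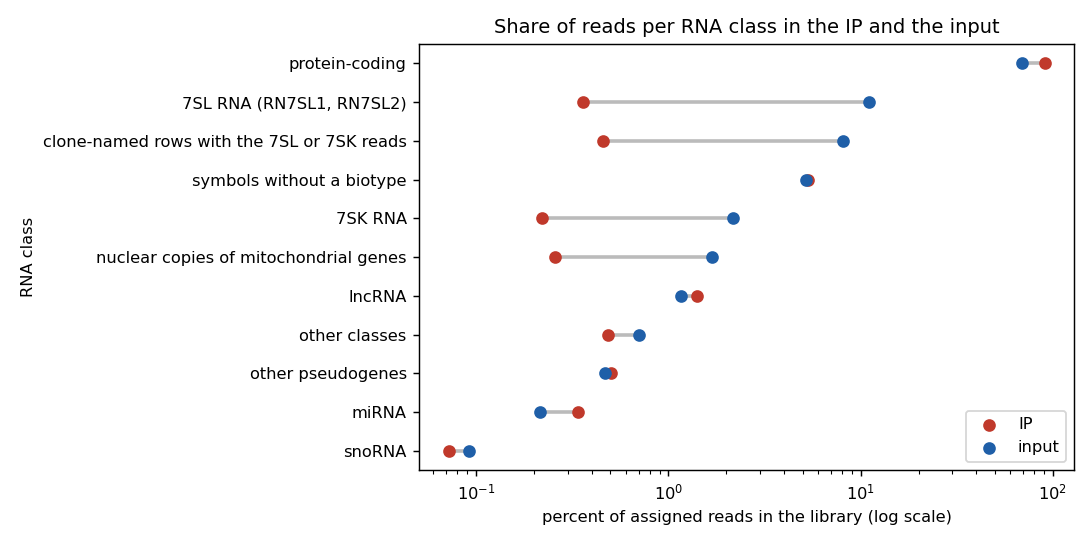
Percent of assigned reads per RNA class (log axis) in the IP library (red) and the input library (blue), 1 library each. Protein-coding genes held 90.6% of IP and 69.2% of input reads, while 7SL RNA held 0.359% and 11.02%.

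The mRNA of SRSF7 itself was near the middle of all genes, with a log2 ratio of 0.15 against a median of 0.14. SRSF7 (chromosome 2) had 807 IP and 343 input reads and carried 0 of the deposited peaks. Its ratio was 1.11, with an interval from 0.977 to 1.26 that includes 1 on the deposited scale. SRSF3, its closest relative among the SR proteins, was at 0.725 times its input level (0.667 to 0.789), also with 0 peaks. YTHDF2, the protein named in the sample protocol, was at 1.23 times (0.942 to 1.62) with 1 peak. These values concern the mRNAs of the proteins and do not show which protein was precipitated.

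Among protein-coding genes with at least 100 reads, a group chosen after the values were seen, genes at both ends of the ranking had ratios far beyond counting error. CREBBP and EP300, the paralogous histone acetyltransferases, were at 5.91 times (interval 5.15 to 6.81) and 4.64 times (3.92 to 5.53) their input level. PTMS, the small acidic nuclear protein parathymosin, was at 5.36 times (4.97 to 5.79), SOX9, a transcription factor of progenitor and duct cells, at 5.13 times (4.51 to 5.87), and POLR2A, the largest subunit of RNA polymerase II, at 5.09 times (4.63 to 5.60). The proliferation marker MKI67 had 20494 IP and 1993 input reads, 4.85 times its input level (4.63 to 5.08), and the chromatin remodeller SMARCA4 was at 4.71 times (4.38 to 5.07). NCL, which encodes the nucleolar protein nucleolin, had the deepest coverage of this group, with 72102 IP and 8789 input reads and a ratio of 3.87 (3.79 to 3.96). At the other end, GCSH of the glycine cleavage system, with 38 IP and 156 input reads, was 8.70-fold lower in the IP (6.07 to 12.8). COX7C, a subunit of cytochrome c oxidase, was 5.32-fold lower (4.67 to 6.07), NDUFB1 of complex I 4.70-fold lower (3.86 to 5.76) and the ribosomal protein gene RPL34 4.69-fold lower (4.01 to 5.49). SMARCA4, GCSH and COX7C share exon bases with another gene on the same strand, so part of their reads may belong to that gene. The other genes named here do not.

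Across the 14057 genes with a mean of at least 1 RPKM, 1592 were at least 2-fold higher in the IP and 1159 at least 2-fold lower on the scale of log2(RPKM + 1), and the median log2 ratio was 0.14 (order-statistic interval 0.13 to 0.15). With reads taken as independent, the counting interval lay wholly beyond 2-fold for 571 higher and 340 lower genes. These numbers are too high if both mates of a pair were counted. The fixed rule for named genes, the 12 highest and 12 lowest with a mean of at least 5 RPKM, gave mostly very short genes. All 12 highest had 0 input reads and 4 to 23 IP reads. The U1 variant RNVU1-2A had 23 IP reads, the microRNA gene MIR4665 and the small nucleolar RNA SNORA49 had 14 each, and SNORD89 had 12. The others were MIR1228, MIR6856, MIR7706, MIR6781, SNORD50B, IGKJ1 and the clone-named AC092670.1 and AL732366.1. The 12 lowest held the Y RNA gene RNY1 (4 IP and 133 input reads), MTRNR2L2 (2 and 52), RN7SL1 at 0.0244 times its input level (0.0238 to 0.02499), RN7SL2 at 0.0395 times (0.0389 to 0.0402) with its duplicate entry AL627171.2, and RN7SL674P at 0.0443 times (0.0316 to 0.0606). RNY3, MIR198, MIR4657, MTND4LP1, RNU6-228P and RNU6-395P, also among the lowest, had 0 IP and 4 to 9 input reads. Higher genes made up 57.9% of the 2-fold calls as deposited, 44.6% after centring on the median, 29.5% after scaling to reads in protein-coding genes and 95.04% after scaling each library to the same RPKM sum. The median log2 ratio of all genes was then 0, -0.17 and 1.24, and the list medians below are to be read against this shift. After either scaling the shift differed in size between genes, because the pseudocount was kept.

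Of the gene lists fixed before the data were examined, the highest relative to genes of like expression were immediate early genes and hepatocyte transcription factors. Immediate early and stress genes were higher in the IP, with a median log2 ratio of 0.62 (interval over genes 0.34 to 1.16). Of the 25 measured members, 10 were at least 2-fold higher and 0 lower. They included JUN, a subunit of the AP-1 transcription factor, at 3.15 times its input level (2.67 to 3.75), SOX9 at 5.13 times and EGR1, with 66 IP and 2 input reads, at 15.6 times (4.14 to 131). The lowest members were FOSL1 at 0.566 times (0.224 to 1.46) and KLF10 at 0.755 times (0.469 to 1.23). Hepatocyte transcription factors and enzymes had a median of 0.61 (0.15 to 1.00), with 6 of 20 at least 2-fold higher and 0 lower. The liver transcription factor CEBPB was at 3.19 times (2.33 to 4.45) and CEBPA at 2.41 times (2.05 to 2.86), while the enzyme TAT was at 0.541 times (0.348 to 0.843). These lists lay at percentiles 99.4 and 98.5 of 10000 random lists matched on mean expression, whose medians centred on 0.18 for both, and their medians were 0.48 and 0.47 after centring, 0.29 and 0.28 with scaling to protein-coding reads and 1.81 and 1.78 with scaling to the same RPKM sum.

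Nuclear-encoded respiratory chain genes and ribosomal protein genes were the lowest lists relative to genes of like expression. The respiratory chain list had a median log2 ratio of -0.58 (-0.78 to -0.16), which turned to 0.62 after scaling to the same RPKM sum but lay below all 10000 matched random lists in both cases. Of its 38 genes, 10 were at least 2-fold lower and 0 higher. COX7C and NDUFB1 were its lowest members, and the complex III core subunit UQCRC1 at 1.75 times (1.49 to 2.05) and the complex I flavoprotein NDUFV1 at 1.61 times (1.42 to 1.82) its highest. Cytosolic ribosomal protein genes had a median of -0.24 (-0.51 to -0.08) at percentile 0.23, or 0.99 at percentile 0.21 after that scaling and -0.47 at percentile 0.01 for the 32 that share no exon bases with another gene. Of 51 genes, 12 were at least 2-fold lower and 1 higher. RPS3A was 3.41-fold lower (3.17 to 3.68) and RPS13 3.69-fold lower (2.77 to 4.95), whereas RPLP2 was at 2.16 times (2.01 to 2.31) and RPS15 at 1.51 times (1.39 to 1.65) its input level.

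Genes of RNA processing went both ways and their lists lay within the range of random lists. The 14 SR protein genes had a median log2 ratio of 0.09 (-0.29 to 0.84) at percentile 34.5, which became -0.05 after centring and -0.29 with scaling to protein-coding reads. With 1 member at least 2-fold higher and 0 lower, they ran from SRSF12 at 0.440 times (0.253 to 0.763) and SRSF3 to SRSF2 at 1.91 times (1.56 to 2.36) and SRSF11 at 2.29 times (2.14 to 2.44). Among 23 hnRNP genes the median was 0.16 (-0.23 with scaling to protein-coding reads), from HNRNPH3 at 0.798 times and HNRNPH2 at 0.859 times to HNRNPUL2 at 1.99 times and HNRNPUL1 at 3.48 times (3.19 to 3.79). Core spliceosome genes had a median of 0.28 (-0.09 with that scaling) with 5 members at least 2-fold higher and 4 lower. The small Sm proteins SNRPF and SNRPD1 were 2.77-fold (2.53 to 3.03) and 2.48-fold (2.28 to 2.70) lower, and the large splicing factors PRPF6 and U2AF2 were at 2.68 times (2.38 to 3.03) and 2.49 times (2.22 to 2.79). The cleavage, polyadenylation and export list had a median of 0.26, against -0.10 with that scaling and -0.06 among genes that share no exon bases, with NUDT21 at 0.534 times, CPSF3 at 0.634 times, CPSF1 at 1.88 times and CPSF6 at 2.07 times. The m6A list had a median of 0.33 (0.03 to 0.85) at percentile 76.9, or 0.0039 with scaling to protein-coding reads and higher with scaling to the same RPKM sum, with the writer complex members ZC3H13 at 2.91 times (2.68 to 3.16) and RBM15B at 2.13 times and with IGF2BP3 at 0.708 times and WTAP at 0.848 times. Translation factors had a median of 0.15 (-0.23 with scaling to protein-coding reads), from EEF1B2 at 0.478 times and EIF3E at 0.530 times to EIF4G1 at 2.98 times (2.82 to 3.16) and EIF3C at 4.03 times (2.90 to 5.75).

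Liver secretory, metabolic and cell cycle lists also lay between the outer percentiles. Hepatocyte secreted proteins had a median of 0.30 at percentile 71.3 (-0.07 with scaling to protein-coding reads), with APOE at 1.70 times and C3 at 1.66 times above APOA2 at 0.569 times and APOC3 at 0.421 times. Cholesterol synthesis had a median of -0.12 at percentile 5.44, against 1.06 with scaling to the same RPKM sum and 0.11 at percentile 33.0 among genes that share no exon bases. It ran from CYP51A1 at 0.398 times and HMGCS1 at 0.479 times to LSS at 2.06 times and SREBF2, the transcription factor that drives the pathway, at 2.03 times (1.70 to 2.45). Endoplasmic reticulum and secretory genes had a median of -0.11 at percentile 5.55 (1.13 with scaling to the same RPKM sum), with SEC61G 3.14-fold lower (2.56 to 3.86), SPCS3 2.16-fold lower, HSPA5 at 1.89 times and HSP90B1 at 2.65 times (2.60 to 2.71). Proliferation genes had a median of 0.29 (-0.08 with scaling to protein-coding reads), from CDK1 at 0.451 times and TTK at 0.413 times to MCM2 at 2.38 times and MKI67. Glycolysis (median 0.30, or -0.05 with that scaling) ran from LDHB at 0.486 times and PGAM1 at 0.643 times to ALDOA at 1.69 times and PKM at 1.77 times, and autophagy and lysosome genes (median 0.07, -0.07 after centring and -0.30 with that scaling) from ATG12 at 0.266 times and MAP1LC3B at 0.549 times to ULK1 at 2.23 times and SQSTM1 at 1.93 times. Replication-dependent histones had a median of 0.31 (-0.07 with that scaling), with H4C8 at 0.541 times, H3C2 at 0.568 times and H2BC21 at 2.71 times. The 245 measured zinc finger genes had a median of 0.13 (0.05 to 0.23), -0.014 after centring, -0.14 with that scaling and 0.34 at percentile 88.3 for the 45 with a mean of at least 5 RPKM, with ZNF627 and ZNF138 lowest and ZNF777 and ZNF629 highest. Hosts of small nucleolar RNAs had a median of -0.14 at percentile 8.27, or 0.78 at percentile 1.51 with scaling to the same RPKM sum, from SNHG6 at 0.308 times and TMEM107 at 0.403 times to SNHG8 at 1.405 times and SNHG12 at 1.36 times. The 8 nuclear long non-coding RNAs had a median of -0.04 (1.14 with scaling to the same RPKM sum), with JPX at 0.714 times, NORAD at 0.863 times, TUG1 at 1.10 times and MALAT1 highest.

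Markers of cell types other than hepatocytes included genes with few reads, such as TYROBP, and genes with many, such as SOX9 and HBB. Among fibroblast markers 2 were measured, COL1A2 at 1.05 times and FBLN1 at 1.37 times, and of the endothelial markers PECAM1 alone, at 0.646 times. The 5 cholangiocyte markers had a median of 0.46, with EPCAM at 0.758 times, SPP1 at 1.31 times and SOX9 highest. The 10 immune markers had a median of -0.20 at percentile 8.97 (0.76 with scaling to the same RPKM sum), with CD3E and TYROBP lowest and MARCO and HLA-DRA highest, each with 26 or fewer reads per library. Among 6 erythroid markers, with a median of -0.47 at percentile 5.97 (0.68 with that scaling, and percentile 1.88 among protein-coding genes), the beta-globin gene HBB had 3593 IP and 2678 input reads, 467 and 738 RPKM, a ratio of 0.633 (0.602 to 0.666). ALAS2 was at 0.664 times (0.490 to 0.903) and SLC4A1 at 0.708 times (0.484 to 1.04), and AHSP had 6 and 2 reads.

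**Figure D2:**
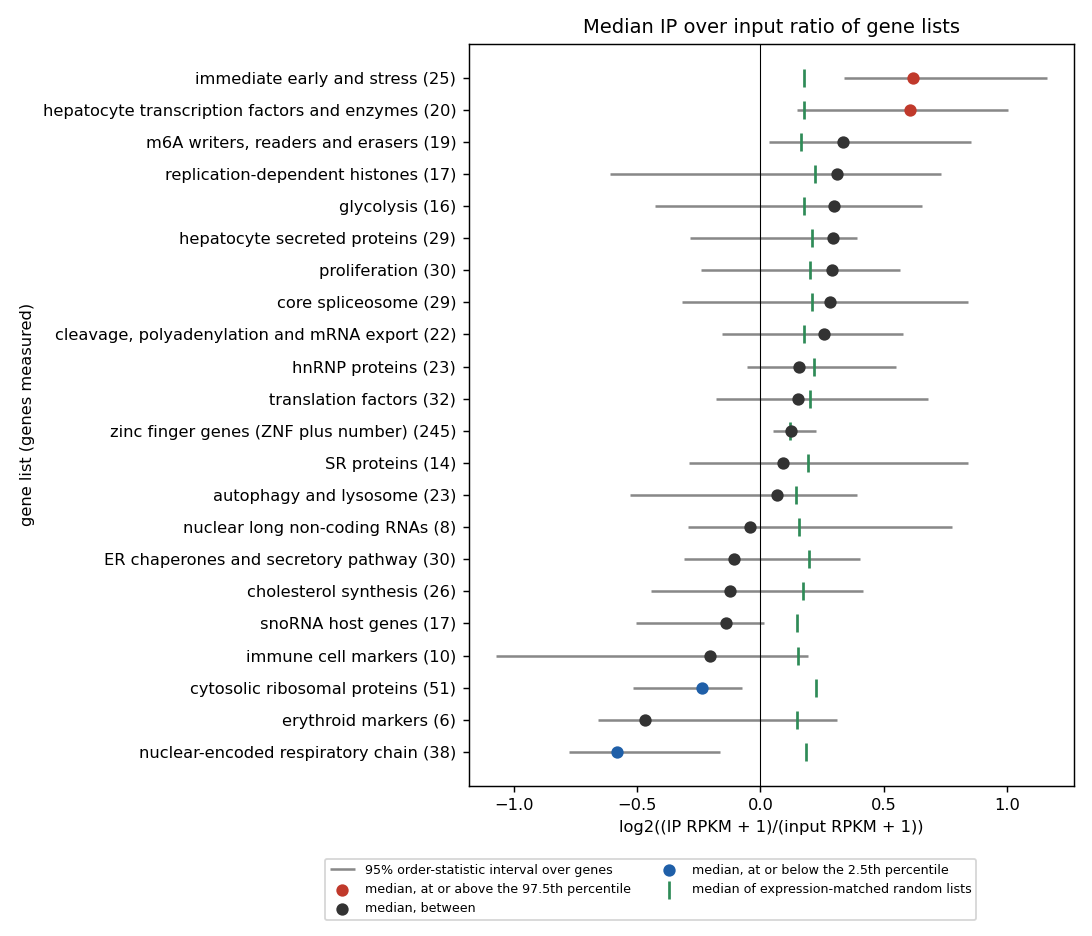
Median log2((IP RPKM + 1)/(input RPKM + 1)) of each gene list with at least 6 measured genes (points), with 95% order-statistic intervals over genes (bars) and the median of 10000 expression-matched random lists (green ticks). Immediate early genes (0.62) and hepatocyte transcription factors (0.61) lie among the highest 2.5% of random lists, and ribosomal (-0.24) and respiratory chain genes (-0.58) among the lowest 2.5%, where they also lie after scaling to the same RPKM sum, which turns both medians positive.

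The deposited list of regions enriched in the IP covered many of the genes that were higher in the IP. It held 7643 peaks, all of which overlapped an exon of a listed gene on the same strand, in 3064 genes. The giant scaffold protein gene AHNAK carried the most, 34, followed by the lipoprotein receptor LRP1 and the ubiquitin ligase HUWE1 with 25 each, the dynein heavy chain DYNC1H1 with 24 and the cytoskeletal linker DST with 23. All 5 genes were higher in the IP, at 2.48, 2.14, 2.98, 3.39 and 2.18 times their input level. Of the genes with a peak, 1439 had 1 and 388 had 5 or more.

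The peaks with the smallest p, named after their values were seen, lay in genes such as MKI67 and NCL, and those with the highest fold in genes such as NR1H2 and UTRN. In the authors' deposited table, the p-value was listed as 0 for 7 peaks, which lay in MKI67 (fold 4.05), SPTBN1 (3.51 and 3.44), NCL (3.29), HSP90B1 (2.84), HSP90AA1 (2.51) and PTMA (2.12). The MKI67 peak spanned positions 128098608 to 128111802 of chromosome 10 on the minus strand and covered 8376 exonic bases. Among peaks at or below the median p, the highest folds in the authors' deposited table were 67.8 in NR1H2, a liver X receptor (chromosome 19, 50376378 to 50376653, an internal exon), 61.5 in UTRN, which encodes utrophin (chromosome 6, 144285700 to 144330902) and 57.2 in the first exon of NR2F1, a nuclear receptor of the COUP-TF family (chromosome 5, 93585046 to 93585396). ANKRD26 followed at 55.1, BCAT2 and DAPK1 at 53.0, and AUTS2, DOCK6, the histone methyltransferase KMT2D and MAP3K4 at 50.9, all folds of the authors' deposited table. The median fold in the authors' deposited table was 2.71, and 390 peaks had a fold above 20. In the authors' deposited table each of these, including the folds from 67.8 to 50.9, is a whole multiple, from 11 to 32, of 2.12, which is also the ratio of IP to input reads. Their order counts such steps, and they are not read here as measured ratios. No genome build is given in the sources used here. Coordinates are those of the deposited tables, in which 99.9% of 19403 genes overlapped the span of the same symbol in GRCh38.p14.

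NCL is given as an example of peaks beside the gene ratio within a single merged gene model. Its 4 peaks on chromosome 2, minus strand, covered most bases of the internal exons between positions 231455130 and 231464398. The strongest, from 231460226 to 231463688 with 1259 exonic bases, had a fold of 3.29 in the authors' deposited table, and the others had folds of 2.65, 2.12 and 2.44. All of these folds lay below the ratio of the whole gene, 3.87 (3.79 to 3.96). The scaling of the folds is not known here, so whether the peaks exceed the rest of the gene cannot be told. In this merged model of all isoforms, the outermost 5′ exon, from 231482684 to 231483641, and most of the last exon carried 0 peaks. The next exon, from 231464336 to 231464484, was overlapped by a peak. Which exon begins the mRNA in these cells was not tested.

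**Figure D3:**
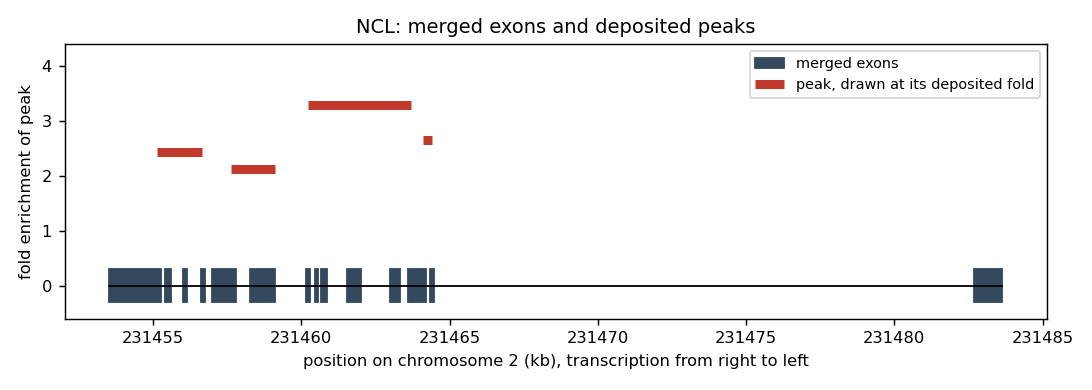
Merged exons of NCL on chromosome 2 (dark boxes, position in kb, transcribed from right to left) with its 4 deposited peaks (red), each drawn at its fold enrichment in the authors' deposited table. The peak from 231460226 to 231463688 has the highest fold, 3.29.

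Genes with a peak were higher in the IP than other genes of the same expression. Their median log2 ratio was 0.71 over 3013 genes against -0.04 over 11044 genes without a peak, and it exceeded all 10000 matched random gene sets, whose highest median was 0.22. Within the 20 expression bins the difference of medians averaged 0.73, from 0.44 to 1.03. Of the genes with a peak, 724 were at least 2-fold higher and 5 at least 2-fold lower, against 868 and 1154 of the genes without. Both tables come from the same 2 libraries and are not independent.

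Peaks were most frequent in hepatocyte transcription factor and proliferation genes and rare in ribosomal protein genes. Of the hepatocyte transcription factors and enzymes, 13 of 20 had a peak (65.0%, against 30.3% in matched random lists, percentile 99.9), among them CEBPB with 2. Of the proliferation genes, 18 of 30 did (60.0% against 31.3%, percentile 99.9), with 7 each in MKI67 and MCM2. The m6A genes stood at 11 of 19 (57.9% against 29.4%, percentile 99.6), with 8 peaks in ZC3H13, and zinc finger genes at 19.2% against 14.5% (percentile 98.2). Of the immediate early genes, 11 of 25 had a peak (44.0% against 26.9%, percentile 96.5). With random lists matched on gene length too, the m6A genes (percentile 82.3) and the zinc finger genes (74.96) lay within the outer percentiles, as they did with the peaks at or below the median p (89.1 and 54.0), while immediate early genes (99.8), hnRNP genes (2.34) and nuclear long non-coding RNAs (1.2) lay beyond them. Ribosomal protein genes had a peak in 3 of 51 (5.88% against 26.0%, percentile 0.02), respiratory chain genes in 5 of 38 (13.2% against 28.8%, percentile 1.28, but 11.1 among unmatched lists) and hosts of small nucleolar RNAs in 0 of 17 (against 27.3%, percentile 0.21, but 2.62 with the peaks at or below the median p). Among unmatched lists, core spliceosome (percentile 99.8), export (98.1) and immediate early genes (99.4) also lay beyond the outer percentiles, while zinc finger genes (19.9) did not. The SR protein genes had a peak in 3 of 14 (21.4%, against 27.7% of matched lists and 43.7%, percentile 3.49, with length matched too).

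Along transcripts, peaks were shifted away from the 3′ end. With the merged exons of each gene cut into 3 equal parts, the 5′ part held 40.2% of peak centres (exact binomial interval 39.1 to 41.3%), the middle part 38.1% (37.0 to 39.2%) and the 3′ part 21.8% (20.8 to 22.7%). In 100 random placements of the same peaks in the same genes, the 3′ part held 32.4% on average and never under 30.7%, and the 5′ part 32.5% and never over 33.7%. These placements took no account of read coverage along the merged exons, parts of which may not be expressed. Uneven coverage could therefore give such a shift, and this was not tested. Internal exons held 73.7% of peaks, last exons 17.7%, first exons 7.17% and genes with a single merged exon 1.44%. Untranslated and coding regions were not separated, since no annotation of them was used here.

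**Figure D4:**
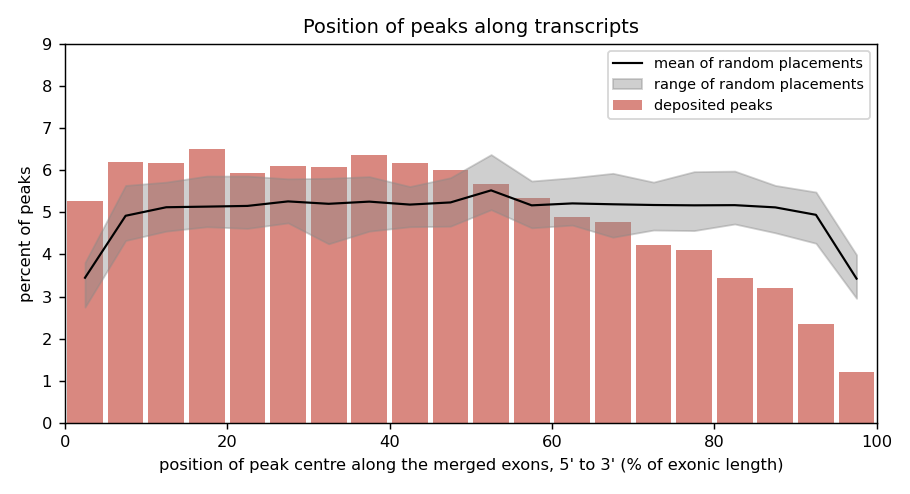
Percent of the 7643 peaks (bars) by the position of their centre along the merged exons of the host gene, in 20 bins from 5′ to 3′, with the mean (line) and range (grey) of 100 random placements in the same genes. Peaks exceed the random range in the 5′ part and lie at 1.22% in the last bin, against 3.42% at random.

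Longer protein-coding genes were higher in the IP and had peaks more often. Across 9857 protein-coding genes, Spearman's rho between gene model length and log2 ratio was 0.21, with genes not being independent replicates. The shortest of 8 length bins had a median log2 ratio of -0.06 (-0.13 to -0.01) and the longest 0.39 (0.35 to 0.43), with a peak in 10.8% and 56.7% of genes. With random lists matched on both expression and gene length, the respiratory chain list stayed below all 10000 random lists and the ribosomal list at percentile 0.02, immediate early genes lay at percentile 99.96 and hepatocyte transcription factors at 98.8. The endoplasmic reticulum list (percentile 0.87) and the cholesterol list (2.33) then also lay below the 2.5th percentile.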

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

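No paired analysis was possible because each group has 1 library and no test was run; the trimmed mean, protein-coding and coverage-based settings, the genes sharing no exon bases, the length-matched lists, the RPKM-sum scaling of lists, the false discovery rate limit and the peaks without folds above 20 were chosen after seeing the data. With a pseudocount of 0.1, and with genes sharing no exon bases, the medians of the 22 lists that have an interval stayed inside it, though among the latter the export, cholesterol and small nucleolar RNA host medians changed sign and others moved by over 1.5 times: ribosomal (-0.47), translation factors (0.32), hepatocyte secreted proteins (0.18) and nuclear long non-coding RNAs (-0.10, 2 genes). A pseudocount of 0.1 moved the zinc finger (0.20) and host (-0.21) medians that far. With a mean of at least 5 RPKM, the zinc finger (0.34), translation factor (0.23), fibroblast (0.42) and endoplasmic reticulum (-0.03) medians also moved that far. Depth limits single genes, with a median of 8 input reads per gene.

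The numbers of genes at least 2-fold higher and lower moved to 816 and 545 with a mean of at least 5 RPKM, 816 and 358 with at least 100 reads, and 794 and 385 for protein-coding genes, all of which test fewer genes. They moved to 8693 and 454 with scaling to the same RPKM sum and to 888 and 2121 with scaling to protein-coding reads. These go with a shift of the median log2 ratio, which became 1.24 and -0.17, the latter a change of sign, against 0 after centring and 0.064 with the trimmed mean. Other settings gave a median of 0.17 (pseudocount 0.1), 0.16 (pseudocount 0.5), 0.12 (no filter), 0.18 (mean of at least 5), 0.23 (at least 100 reads) and 0.17 (protein-coding genes). With the RPKM-sum scaling, all negative list medians became positive, among them the ribosomal (0.99) and respiratory chain (0.62). With protein-coding scaling, all positive ones became negative except those of the m6A, immediate early, hepatocyte transcription factor and cholangiocyte lists. The zinc finger median changed sign after centring (-0.014) and with protein-coding scaling (-0.14), and centring also turned the SR protein and autophagy medians; each follows from the shift. A pseudocount of 0.1 gave 2373 and 1712 genes, within 1.5 times of the main counts.

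At or below the 2.5th percentile lay 4 lists with length matching (also the endoplasmic reticulum and cholesterol lists) and 4 among protein-coding genes (also the endoplasmic reticulum list, 2.08, and erythroid markers, 1.88), against 2, and 5 lists for peak shares with length matching, against 3; the cause was not tested beyond the matching itself. Peaks numbered 1401 at a fold of at least 4 (median fold 6.24), 3824 at or below the median p (2.58) and 4609 at a false discovery rate of at most 0.05 (2.62), and without folds above 20 the median fold was 2.64, each by construction. The 5′ part of transcripts held 38.8% of the peaks at or below the median p and 38.0% of those with a fold of at least 4, the middle part 39.9% of the former and the 3′ part 24.7% of the latter; the cause was not tested. The motif alternatives were not run because no genome was used here, and the choice between entries of the same symbol did not arise because each symbol had 1 entry. The trimmed mean was set down for a table of counts only and was run on recovered reads instead.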

Other observations

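The tests of histone classes, single-exon genes, symbol families, gene length, RNA length, poly(A) selection and tissue transcripts were chosen only after the result was seen. Histone genes are given here by class, without a test of the difference between classes. Linker histone H1 genes had a median log2 ratio of 1.06 (-0.32 to 1.52) over 7 genes, with 4 at least 2-fold higher, among them H1-10 at 2.98 times its input level (2.31 to 3.89) and H1-4, with 6051 IP reads, at 2.16 times (2.03 to 2.29). H2B genes had a median of 0.56 (0.41 to 0.99) over 18 genes, and 17 of them lay above 0, while with scaling to protein-coding reads the H2B median was 0.18 and that of H1 0.70. H2A, H3 and H4 genes had medians of -0.14, -0.40 and -0.49, which became 1.10, 0.82 and 0.75 with scaling to the same RPKM sum, while H1 (2.30) and H2B (1.81) stayed above them. Protein-coding genes with a single merged exon, which include JUN, JUND, CEBPA, CEBPB and SOX4, had a median of 0.32 (0.24 to 0.42) over 239 genes, or 0.010 with scaling to protein-coding reads. As deposited, this lay above all 10000 random lists matched on expression and length, whose medians centred on 0.04.

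A scan of 107 families of protein-coding genes sharing a symbol stem, made after the data were seen, found 16 among the highest and 16 among the lowest 2.5% of random lists, where chance gives 2.68 per side. With length matching, 14 and 12 families lay there. Golgins (GOLG, median 0.80), myosins (MYO, 0.77), histone demethylases (KDM, 0.74), DEAH-box helicases (DHX, 0.63) and kinesins (KIF, 0.59) were high, with positive medians under each scaling. Cytochrome c oxidase (COX, -0.74), complex I (NDUF, -0.49), Sm-like (LSM, -0.47) and mitochondrial ribosomal proteins (MRPS, -0.43, and MRPL, -0.34) were low, though scaling to the same RPKM sum, which moves the median of all genes to 1.24, turned them to values from 0.45 (COX) to 0.77 (MRPL). By chromosome, medians of protein-coding genes ran from -0.05 on chromosome 13 (-0.17 to 0.04) and 0.02 on chromosome 18 to 0.43 on chromosome 22 (0.34 to 0.52) and 0.45 on chromosome 19 (0.39 to 0.52).

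The low IP level of respiratory chain and ribosomal protein mRNAs is open to technical explanations. Gene model length as the whole cause is excluded, because among lists matched on expression and length both stayed at or below percentile 0.02, though the length of the mature mRNA was not tested. Adding the reads of 245 named pseudogenes to their 57 parent genes left a median of -0.33 (-0.68 to -0.08), below the 0.17 of all genes, so reads moved to pseudogenes do not account for it. Lists matched on chromosome and expression left both at or below percentile 0.08, so the trend across chromosomes is not enough either. Base composition within genes remains open, and no biological explanation was tested.

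7SL, 7SK and RNase P RNA were lower in the IP than RNAs of like length outside the 7SL family, though the shorter RNY1 was as low (-5.92). The other 5 such single-exon non-coding genes of 200 to 400 bases with at least 100 reads lay between -2.03 (SCARNA10) and -0.08 (SNORA73B). All lay above the -2.84 of RPPH1, the least reduced of 7SL, 7SK and RNase P RNA. These RNAs were grouped after their low ratios were seen, with RMRP (-0.74) left among the other 5, so this order is partly fixed by the grouping. RNAs of like length still differed this widely, so that length is not the whole cause. Poly(A) selection that differed between the libraries would by itself lower replication-dependent histone mRNAs, which lack a poly(A) tail, by as much. Their list had a median of 0.31 (-0.61 to 0.73). Enrichment of histone mRNAs in the IP could offset such a loss, and histone classes differed, with medians from 1.06 (H1) to -0.49 (H4). Differing poly(A) selection is therefore not excluded. Absence of binding may account for the difference, but without a control IP no biological explanation was tested.

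Both libraries held transcripts best known from blood and heart muscle: of 53 such genes, 34 had at least 10 reads in both libraries, against 3 of 27 genes of other tissues. The sets were regrouped after values were seen: the comparison set first held 34 genes, of which 6 passed, until its 7 muscle genes were taken out and a heart set was drawn up from the high MYH6 (2164 IP and 1612 input reads), MYH7 (1530 and 1105) and TNNT2 (627 and 448). Over all 52 of these genes in the table, with no limit on reads, the pooled ratio was 0.635 times the input for blood (0.613 to 0.657) and 0.645 times for heart genes (0.618 to 0.673). With reads taken as independent, 7 of the 39 with at least 20 reads in all lay off the common ratio beyond counting error, such as CXCR1 (20 and 2), LAPTM5 (34 and 8), HBA2 (586 and 366) and LYZ (714 and 637). Counting both mates of a pair would by itself widen such departures, so whether these genes lie off the common ratio cannot be told. The spread of all 52 genes (chi-square of 2.33 per degree of freedom) lay at percentile 0 of random genes matched on read number (median 20.99, lowest 4.46). Mates counted singly would raise the chi-square of these and of the random genes. Blood genes alone had 2.73 against a lowest random value of 3.802. Heart genes alone had 1.72, close to their lowest random value of 1.76. Such a spread grows with read number, and how closely the random genes matched the most deeply read genes was not tested. Whether the cells themselves transcribed these genes therefore cannot be decided from it. Transcripts abundant in heart muscle cells or leukocytes gave mixed values. With reads again taken as independent, 8 of 14 heart transcripts lay below 0.1 times the MYH7 input RPKM beyond counting error. They included MB, MYL7, TCAP, PLN and NPPA with 0 input reads and MYL2 with 8. Others did not, such as TNNC1 at 50.7% and TNNT2 at 33.3% of MYH7. Of 6 leukocyte transcripts, 5 lay this far below S100A9, among them S100A8 with 6 input reads, while LYZ stood at 80.2%. The limit of 0.1 times was set after the values were seen. The low transcripts are unlike RNA of these cells as such, but neither source is excluded. RNA of red blood cells, with 0 of 2 transcripts this far below HBB, cannot be told apart from other sources, and no other biological explanation was tested.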
